A study of Gallus gallus with 3 samples.

How the data were processed

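Poly(A) RNA was isolated from tracheal scrapings with an oligo-dT mRNA kit, reverse transcribed with random hexamers, made double stranded, sonicated, and amplified by PCR into indexed libraries that were sequenced on an Illumina HiSeq 2000, per the labels' protocols. No step described there keeps the strand of the RNA or adds molecular identifiers, so amplified copies of a fragment cannot be told from separate molecules and overlapping genes cannot be separated by strand. Bowtie, bedtools and DESeq are named in the submitters' processing notes, without their roles or versions. The genome build, the read filters and the settings of these tools are not given in the sources used here.

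Of the deposited tables, the comparison table of the authors was used. It holds, per the file headers, a mean for each of 2 conditions and over all libraries, a fold change, its log2 value, a p-value and an adjusted p-value for each Ensembl gene identifier. The means are a signal on the scale of counts divided by library size factors, as deposited by the authors. The authors' fold change is the ratio of condition B to condition A, checked within 1e-06 on the log2 scale for all 17934 genes, and the log2 values of the authors were reversed in sign so that positive values mean higher in inoculated birds. The authors' adjusted p-value equalled a Benjamini-Hochberg adjustment of their p-value over all 17934 genes within 1e-06. No gene has a value of 0 in either condition as deposited.

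The condition letters carry no label. They were assigned from the number of libraries behind each mean, as the weights of the overall mean show it, and the number of libraries per group in the labels. A separate table of normalised values per library has 3 columns whose names match no label of any sample. A pair of these columns averages to the mean of condition A and the remaining one equals condition B, apart from rounding, which would make the remaining one the control. Per-library columns were given to single samples only by name, however, so these 3 columns were not used here. This is a stricter rule than the one used for the condition means. The limma, gene-list and per-pool analyses set down before the data were examined needed either those columns or gene symbols and were not run, and no inoculated pool was left out in turn. The calls reported are therefore those of the authors' table, whose estimate of spread was not checked here. P-values measure only the spread the authors' model assigned to these pools, and the single control pool is assumed to vary as that model states.

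From the table, genes were counted by adjusted p (threshold 0.05), direction, fold and abundance. Counts of genes at least 2-fold apart used log2 of the value plus a pseudocount of 1 and an overall mean of at least 10, a scale that understates the change of scarce genes. The planned version of this count, which required the change in both inoculated pools, was replaced by one on the condition means. Alternatives were pseudocounts of 0.5 and 5, no abundance filter, an overall mean of at least 50, and rescaling of the control by equal totals, by equal upper quartiles (75th percentile), or by an unweighted trimmed mean of log ratios (30% trimmed from each end of the log ratios and 5% from each end of abundance). For the calls, p-values were readjusted over genes with a mean of at least 50, and, chosen after the data were seen, of at least 10, and thresholds of 0.1 and 0.01 were tried.

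The rule for naming genes, set before the data were examined, asked for genes with a symbol, an overall mean of at least 50, an adjusted p under 0.05 and both inoculated pools on the same side of the control, ranked by the size of the change in each direction. No symbols were matched and the per-library values were not used, so the first 2 identifiers in each direction by the remaining criteria are given. The 22 gene lists fixed beforehand for airway cell types and immune pathways could not be applied to identifiers without symbols.

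Control values were divided by the smallest one to recover whole steps, and 100% lay within 0.001 of a whole number. A 95% exact Poisson interval was computed from the steps for the named genes, and is reported for those above the lowest step. Control values at or under 3 steps were counted as near the floor. Depth in the control, 6662211 steps, limits the precision of every fold. The intervals cover counting error in the control only and leave out that of the inoculated libraries. The steps were tested on simulated data with 200 changed genes. The adjustment step recovered 100% of changed genes with 6.98% false calls over 17934 genes. Those changed genes were given a large assumed shift, so near-complete recovery was built in. The 2-fold step recovered 97.0% of genes raised 4-fold and 99.0% of genes lowered 4-fold, with 2.56% of unchanged genes past 2-fold, over 12421 genes. The simulated control was first rescaled by the trimmed mean of log ratios, unlike the control in the main 2-fold count. The 2-fold simulation drew its changed genes only from abundant genes, and its spread was an assumed value not fitted to these data. These rates therefore check the steps and do not give error rates for the deposited genes. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9.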

Results

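Messenger RNA was sequenced from tracheal scrapings of specific-pathogen-free white leghorn chickens (Gallus gallus), the upper-airway tissue in which infectious laryngotracheitis virus, a herpesvirus of chickens, replicates. Birds received either a live laryngotracheitis vaccine or only its sterile diluent, 200 µL per bird through the eyes and nostrils at 21 days of age, and tissue was taken 6 days later. The series holds 3 libraries: 1 control library and 2 inoculated libraries, each made from a pool of 5 birds. The accompanying descriptions differ on the number of birds, since one gives 10 inoculated birds split over 2 pools and another gives 5 inoculated birds. If only 5 birds were inoculated, the 2 inoculated libraries would not be independent, and the spread behind every call reported here would be technical. Because there is 1 control library, no comparison here has a replicate on the control side. The labels' only named question is the vaccine's effect on the tracheal transcriptome, with antigen presentation by class I and class II major histocompatibility molecules in the series title.

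Gene-level values came from the authors' deposited table, which lists 17934 chicken Ensembl gene identifiers with the mean normalised count of each condition, their fold change, a p-value and an adjusted p-value. Its conditions are named only A and B. For all 17934 genes the overall mean equalled 2 parts A and 1 part B within 1e-06, so A averages 2 libraries and B is 1 library. A was therefore read as the inoculated birds and B as the control, because the labels give 2 inoculated libraries and 1 control library. Fold changes are given below as inoculated over control, the reverse of the table's own direction. The table pairs no identifier with a gene symbol. The gene reference at hand held no Ensembl identifiers, so the match of 0 of the 17934 identifiers was fixed in advance. Genes are therefore counted as groups and only 4 are given by identifier. Whether genes of the antigen presentation pathways were among those that changed was not analysed here for that reason.

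Control depth could be read from the table itself. Every control value was a whole multiple of 1 step of 1.02 normalised counts, within 0.001 of a step, and the control column summed to 6662211 steps. The steps of the inoculated means mix 2 libraries, and their depths are not reported here. Normalised counts summed to 6784638 in the control and to 7391217 in the inoculated mean, a ratio of 1.09. A few genes took much of each total. The 10 most abundant genes held 25.4% of the control total and 22.3% of the inoculated total, and 7 genes were in both sets of 10. The most abundant control gene alone held 9.37% of the control total, 635641 normalised counts. The same gene held 2.64% of the inoculated total, 194799 normalised counts, where it had rank 3. This difference of -1.71 on the log2 scale did not pass the test in the authors' deposited table (p = 0.124, adjusted p = 1).

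The comparison of inoculated with control trachea asks which transcripts differed 6 days after vaccination. More genes were higher than lower in the inoculated birds. At an adjusted p under 0.05, the authors' deposited table called 147 of 17934 genes, or 0.820%. Of these, 121 were higher and 26 were lower in the inoculated birds. The genes called higher had a median fold change of 15.3 and ranged from 5.43-fold to 322-fold, the upper end being a gene at the lowest control value. Those called lower had a median fold change of 6.46 and ranged from 4.05-fold to 81.4-fold, the upper end being a gene at the smallest inoculated mean. No SD or standard error accompanies these folds. The table used gives only condition means, the deposited per-library columns were not used, and the control mean rests on 1 library.

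**Figure D1:**
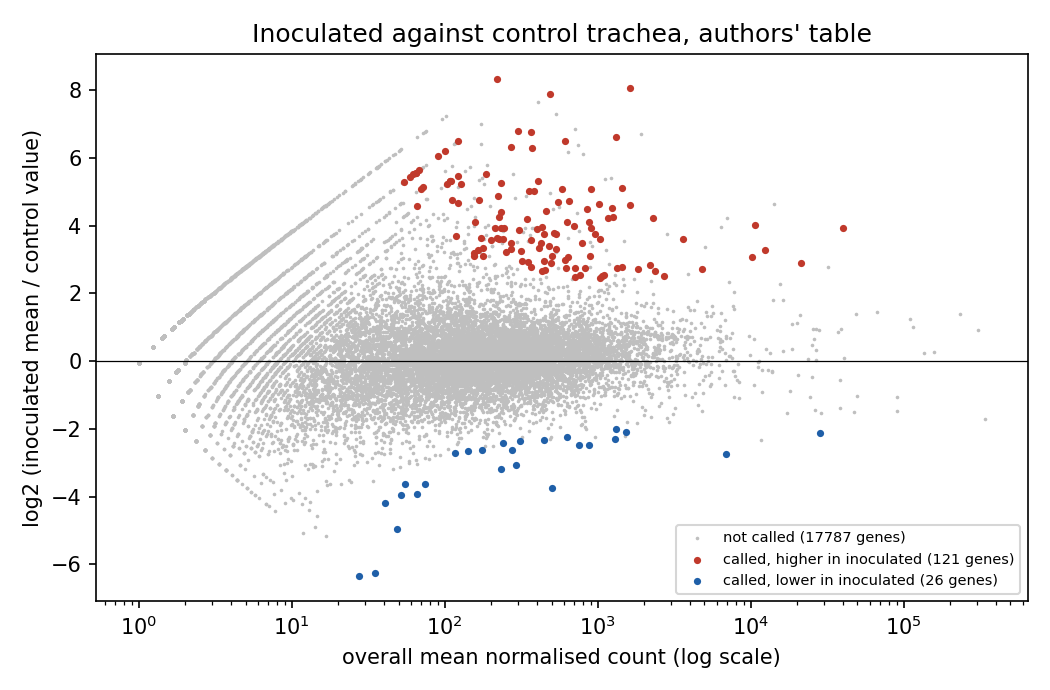
Each point is 1 of the 17934 genes, placed by its overall mean normalised count (horizontal, log scale) and by the log2 ratio of the inoculated mean to the control value (vertical). The 121 genes called higher in the inoculated birds (red) range from 2.44 to 8.33 and the 26 called lower (blue) from -6.35 to -2.02, as rounded, while uncalled genes (grey) spread more widely at low counts, where values fall on lines of whole steps.

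By median, the genes called higher were scarce in the control and moderately abundant after inoculation. Not all were, since 26 of the 121 had an overall mean of at least 1000. In the authors' deposited table the median of all 121 was 38.7 normalised counts in the control and 601 in the inoculated birds. Together they made up 0.322% of the control total and 3.23% of the inoculated total. All 121 were at least 4-fold higher, 97 were at least 8-fold higher and 56 were at least 16-fold higher. In 13 of them the control value was 3 steps or fewer, so their folds rest on very few control reads. The 26 genes called lower had a median of 599 normalised counts in the control and 91.3 in the inoculated birds. They made up 1.41% of the control total and 0.267% of the inoculated total. All 26 were at least 4-fold lower, 11 were at least 8-fold lower and 4 were at least 16-fold lower. Those 4 all had an overall mean under 50, so their folds rest on low inoculated values.

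The gene with the largest called increase by the deposited ratio, ENSGALG00000012531, had a mean of 328 normalised counts in the inoculated birds and 1 step in the control. Its log2 ratio was 8.33 and its adjusted p in the authors' deposited table was 6.84e-05. The control value is the lowest in a table that holds no 0, so the size of this ratio is not measured, and no interval is given. ENSGALG00000014585 had 2450 normalised counts in the inoculated birds against 9.17 in the control. This is a log2 ratio of 8.06 (95% exact Poisson interval of 7.14 to 9.19 from the control count alone), and the deposited table's adjusted p was 0.00166. The order of these genes turned with a pseudocount of 1, which gave log2 ratios of 7.35 for ENSGALG00000012531 and 7.91 for ENSGALG00000014585. Among genes called lower with an overall mean of at least 50, ENSGALG00000006591 fell from 138 normalised counts in the control to 8.89. Its log2 ratio was -3.96 (control counting interval -4.20 to -3.71) and its adjusted p in the authors' deposited table was 0.00932. ENSGALG00000013587 fell from 174 to 11.5 normalised counts, a log2 ratio of -3.92 (control counting interval -4.14 to -3.70), with a deposited adjusted p of 0.00514. These intervals take each step as 1 read, which would be 1 read too many if a count had been added to every gene. They cover counting error in the control library only and leave out variation between birds and pools.

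Calls depended on abundance. None of the 5528 genes with an overall mean under 10 was called in the authors' deposited table, and 4 of the 2785 genes from 10 to under 50 were called, all of them lower in the inoculated birds. The share called was 0.837% of the 4419 genes from 50 to under 200, 1.76% of the 4271 genes from 200 to under 1000 and 3.33% of the 931 genes at 1000 or more. In each of these last 3 ranges the genes called higher outnumbered those called lower, by 30 to 7, 65 to 10 and 26 to 5. The ranges do not treat the directions alike. Because the overall mean is 2 parts inoculated and 1 part control, a lower gene has a smaller overall mean than a higher gene of the same fold and peak value.

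**Figure D2:**
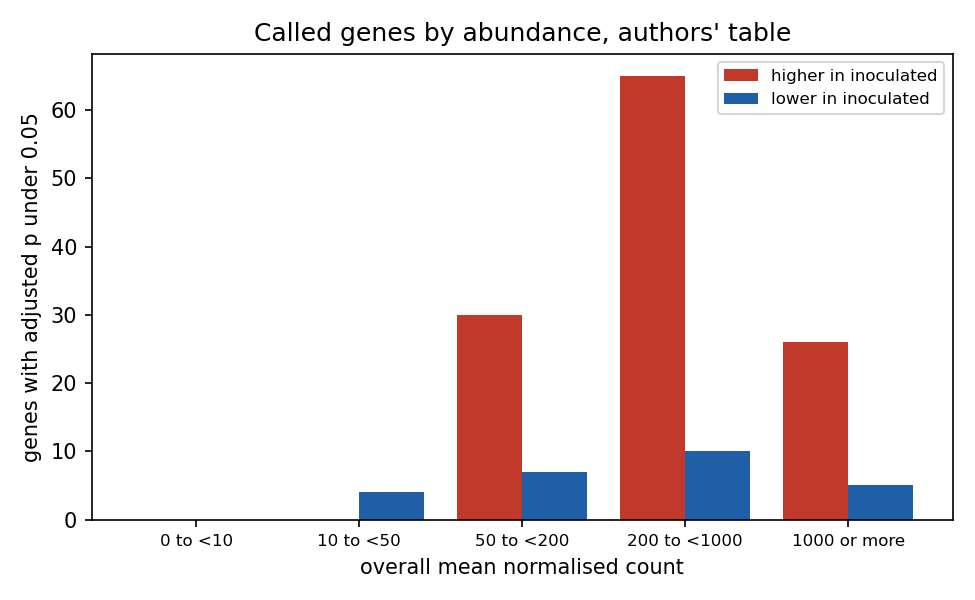
Bars give the number of genes with an adjusted p under 0.05 in the authors' deposited table (vertical), by overall mean normalised count (horizontal) and by direction. Genes called higher in the inoculated birds (red) number 30, 65 and 26 in the 3 upper ranges, against 7, 10 and 5 called lower (blue), and no gene under a mean of 10 was called.

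Large folds were far more numerous than calls. Among the 9621 genes with an overall mean of at least 50, 468 were at least 4-fold higher and 85 at least 4-fold lower in the inoculated birds. The authors' deposited table called 121 of those 468 genes (25.9%) and 22 of those 85 (25.9%). At 8-fold or more, it called 97 of 256 higher genes (37.9%) and 7 of 10 lower genes (70.0%). A fold of that size was therefore not sufficient for a call in either direction. Before adjustment, 854 genes had a p under 0.05 in the authors' deposited table, 515 higher and 339 lower, where uniform p-values would give 897. The genes tested include 2318 at the smallest value in both conditions. Among the 9621 genes with an overall mean of at least 50, the table gave 736 with a p under 0.05, or 7.65%.

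Most genes were less than 2-fold apart between the condition means. The median log2 ratio over the 12406 genes with an overall mean of at least 10 was 0.12, with quartiles of -0.42 and 0.67. With a pseudocount of 1, 1985 of these genes were at least 2-fold higher and 1223 at least 2-fold lower in the inoculated birds, a description of condition means with no test. Here too, a high value in 1 inoculated pool can place a gene on the higher side. That split, 61.9% higher, moved to 54.0% after rescaling by a trimmed mean of log ratios, 52.9% with equal upper quartiles and 53.8% with equal totals.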

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

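The number of called genes moved little with the abundance filter. Readjusting the p-values over genes with a mean of at least 50 gave 161 calls, 143 of them among the original 147, and readjusting over genes with a mean of at least 10, an alternative chosen after the data were seen, gave 159 calls, with all 147 among them. The thresholds of 0.1 and 0.01 were also chosen then. The first gave 173 calls and the second 96, of which 85 were higher and 11 lower in the inoculated birds. A stricter threshold gives fewer calls by construction, but the cause of the larger loss among lower genes was not tested. The share of calls that were higher in the inoculated birds lay between 81.1% and 88.5% over all these settings. Requiring a mean of at least 50 left 1288 genes at least 2-fold higher and 717 at least 2-fold lower, because fewer genes were counted. The other pseudocounts, the missing filter and the rescalings kept these 2-fold counts between 1714 and 2625 higher and between 1089 and 1677 lower, against 1985 and 1223. The rescalings shifted log2 ratios by between -0.14 and -0.12 before the pseudocount was added, and by less for scarce genes after it. The deposited log2 ratio of ENSGALG00000012531, 8.33, fell to 7.76 and 5.79 with pseudocounts of 0.5 and 5, and to between 7.28 and 7.29 under the rescalings, whose values include a pseudocount of 1. ENSGALG00000014585 was the higher of these 2 genes under each of these settings, at 7.99, 7.44 and 7.79 to 7.80. With a pseudocount of 5, ENSGALG00000006591 moved from -3.96 to -3.37 and ENSGALG00000013587 from -3.92 to -3.44, both outside their control counting intervals. Those intervals leave out counting error in the inoculated means, which were only 8.89 and 11.5 normalised counts. No paired analysis was possible because the control group has 1 library and the columns used carry no replicate number. TMM with weights, edgeR, DESeq2 and limma variants and leaving out a pool, all listed beforehand, were not run, because the deposited per-library columns were not used here. Depth limits what can be said of scarce genes: none under a mean of 10 was called in the authors' table.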

Other observations

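Of the tests below, those of 4-fold counts and of the lowest step were chosen only after the result was seen. The 2-fold test of scaling was first set for the called genes, and was kept for the 2-fold excess because every called gene differed by at least 4-fold. The excess of genes called higher over genes called lower in the inoculated birds, 121 to 26, is a ratio of 4.65. Whether scaling between the conditions contributed to it was not settled. With at least 50 normalised counts, the ratio of genes at least 4-fold higher to genes at least 4-fold lower was 5.51 as deposited. The lowest value over 3 rescalings was 3.75, so an excess of large folds remained among the genes that pass this filter. The filter itself favours higher genes, because the overall mean is 2 parts inoculated and 1 part control. How much of the ratio comes from the filter was not tested. That ratio includes genes not called, and 1 high inoculated pool can raise it. The rescalings, with log2 shifts of -0.14 to -0.12, were too small to bring any called gene under 4-fold. The authors' p-values were not recomputed after rescaling, so the split of the calls itself was not tested. Control values near the floor do not account for the excess of calls. Of the genes called higher, 10.7% had a control value of 3 steps or fewer. The other 108 still outnumbered the genes called lower by 4.15. The control side holds 1 library, so a single control pool that differed from others by chance cannot be told apart from an effect of the vaccine, which is also untested here as a biological explanation.

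Whether the smaller excess at 2-fold, 1985 to 1223 genes or a ratio of 1.62, came from the authors' scaling was not settled. After rescaling the ratio fell to between 1.12 and 1.17. Rescaling reduces a shift shared by most genes whatever its source, so this fall does not identify the cause. The lowest ratio, 1.12, lies between the values set beforehand for and against the authors' scaling, so that explanation stays open. The most abundant control gene bears on totals: without it the ratio of inoculated to control totals rose from 1.09 to 1.17.

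No gene has a value of 0 in either condition. In the control, 3638 genes sit at 1 step, 679 at the next and 393 at the one after. The lowest step thus holds 5.36 times as many genes as the next, against 1.73 for the following pair, and 12.9% of all genes sit at the smallest value in both conditions. This pattern is consistent with 1 count having been added to every gene before scaling, as a hypothesis that no header or label records. If so, the control total would be 6644277 reads, and the control library would hold 0 reads of ENSGALG00000012531.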
